A study of Mus musculus with 10 samples.

How the data were processed

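Small RNA was sequenced in 10 samples of heart from male C57Bl6N mice, taken 1 week after transverse aortic constriction, a surgical narrowing of the aorta that loads the left heart with pressure. Per the labels, 5 libraries came from CITED4 knockout hearts and 5 from floxed control hearts, in which the gene carries recombination sites but is intact. RNA was extracted from frozen hearts and libraries were made with a NEXTflex small RNA kit, per the labels' protocols. All 10 libraries were taken after the operation, so the response to the operation itself was not analysed here. CITED4 messenger RNA is not part of miRNA counts, so the genotypes are those the labels give.

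The authors deposited 2 tables with 1139 mature mouse miRNAs and 10 columns each. The first holds raw read counts per miRNA, which the authors deposited without normalization. The second is a linear signal: each value equals the deposited count divided by 1 factor per library, within a relative tolerance of 1e-09 in all 10 libraries, and that factor equals the DESeq2 size factor computed here from the counts. The submitters' processing notes name cutadapt 1.10, Bowtie, STAR, DESeq2 and the GRCm38 build, without a role for each. The miRNA annotation release, the rule for reads that match several miRNAs and any use of molecular identifiers are not given in the sources used here. Intervals therefore cover the spread between libraries or counting error, not amplification bias. Each column was matched to its library through the title, which gives the genotype and the replicate number. Nothing in the labels states whether the 5 libraries of a group came from 5 animals, so p-values measure the spread between these libraries, which may be technical. Counts of any 2 libraries of a group differed by far more than sampling noise, with a chi-square per degree of freedom of at least 124 among controls and 242 among knockouts, so each was counted as 1 replicate.

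Of the 1139 miRNAs, 34 had no count in any library. The filterByExpr function of edgeR kept 457 miRNAs, which held 99.99% of all counts, and 682 were not tested. Among those tested, 15 rows had counts identical to another row, such as miR-486a-5p with miR-486b-5p and miR-199a-3p with miR-199b-3p. These pairs share a mature sequence or their reads, so their members cannot be told apart and the reads enter library totals repeatedly. Library totals were scaled with TMM factors, and CPM values (counts relative to these scaled totals) use them. For log2 CPM a prior count of 2 was added.

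Knockout was compared with control by edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with genotype as the only term and Benjamini-Hochberg adjustment over 457 miRNAs, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic, and 95% intervals use the t distribution with the degrees of freedom of the fit. Before the data were examined, 16 lists of miRNAs were fixed (families, genomic clusters, markers of cell types, and miRNAs linked to cardiac hypertrophy). Lists were tested with camera (limma 3.58.1) at a preset correlation between miRNAs of 0.01 and adjusted over the 16 lists. Each list was also tested with an estimated correlation, with fry, whose directional p asks whether the members move, on balance, one way, and, chosen after seeing the data, with an exact two-sided permutation test of its mean log2 CPM per library. With 5 libraries against 5 the smallest p of that permutation test is 0.0079. Library totals and the share of the most abundant miRNA were compared by the same exact test. Some lists share members: 6 of the 10 fibroblast, 3 of the 7 endothelial and 2 of the 4 erythroid miRNAs also stand in another list, such as miR-21a-5p in that of pathological hypertrophy. All lists were measured in RNA of whole heart samples, so a list is not specific to its cell type.

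The miRNAs named in the text follow a rule fixed before the data were examined. It takes up to 10 per direction past the threshold and, where fewer than 5 pass, the 5 with the smallest p, together with 13 miRNAs chosen in advance and up to 4 members of each list with the smallest p. A few others were chosen after their values were seen: the Dlk1-Dio3 members with a lower mean, and those marked so in the closing section. Hairpin positions are from RefSeq on GRCm38.p6 and host genes from GENCODE release M21 on the same build. Of the 457 tested miRNAs, 447 matched a hairpin by name. Host genes were read on the strand of the hairpin.

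The same replicate numbers, 1 to 5, occur in both groups, and the labels do not say what a number marks. For that reason the numbers were not taken to pair the libraries, and a block was run as an alternative only. Of the 5 same-number pairs, 3 had deviations from their group means that correlated above 0.1. These were numbers 1, 2 and 4, at 0.45, 0.38 and 0.40, while numbers 3 and 5 were at -0.08 and -0.12. The fits were tested on simulated data drawn with the means, library sizes and dispersions of these libraries and with independent noise for each miRNA. The simulation of this comparison, run on 452 miRNAs, changed 66 miRNAs per fold size. Of these, 50.0% were recovered at 1.5-fold, 80.3% at 2-fold and 100% at 4-fold, with 1 false call among 254 unchanged miRNAs. With so many miRNAs changed at once, the adjusted threshold is easier to pass than where few change. Noise shared between miRNAs was not simulated either, so these shares may overstate recovery in the real libraries. Alternatives covered 3 other normalizations, 2 other filters, DESeq2 1.42.0, limma-voom with and without sample weights, limma on log2 of the deposited normalized values with a pseudocount of 1, the block, the fit without the most abundant miRNA, and each library left out in turn. Chosen after seeing the data were the first principal component or 1 surrogate variable (sva 3.50.0) as a covariate, thinning of all libraries to the smallest total of 7526091 counts, and counting identical rows once.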

Results

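miRNA levels were measured by small RNA sequencing in hearts of CITED4 knockout mice and floxed controls 1 week after transverse aortic constriction. CITED4 is a transcriptional co-regulator that binds histone acetyltransferase coactivators. The libraries held 9936086 ± 1484042 counts in the control group and 13090707 ± 4480297 in the knockout group (SD, n = 5 each), with a range from 7526091 counts in control replicate 3 to 18369483 in knockout replicate 5. This difference in depth was within the spread between libraries (exact two-sided permutation test, p = 0.24). Between 678 and 785 miRNAs had at least 1 count in a library. At these totals, a count of 0 allowed a level of up to 0.399 CPM (3 counts) in the shallowest library. This level was taken relative to the unscaled library total, without the TMM factor that enters the other CPM values. The muscle miRNA miR-1a-3p took 32.5% ± 5.79 of all counts in controls and 30.7% ± 4.66 in knockouts (exact two-sided permutation test, p = 0.61). The 5 most abundant miRNAs together took 53.7% ± 4.61 and 54.1% ± 2.20.

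The single comparison of the design asks which miRNAs differ between CITED4 knockout and control hearts under pressure overload. The mean levels of all 5 miR-30 family members were lower in knockout hearts, at 0.651 to 0.797 of the control level, and 36 of the 39 tested miRNAs of the imprinted Dlk1-Dio3 cluster had higher means, with a median of 1.39-fold. Muscle miRNAs miR-133a-3p and miR-133b-3p were at 0.727 and 0.678 of the control level. None of these miRNAs passed the test singly. Of 457 miRNAs, 0 were raised and 0 were lowered at an adjusted p of 0.05 in edgeR's quasi-likelihood test, with a smallest adjusted p of 0.64. At an unadjusted p under 0.05 there were 29 miRNAs, 13 with a higher and 16 with a lower mean in knockout. This count was 84 without control replicate 1 and 65 without knockout replicate 4, and 16, 10, 6, 8, 13 and 18 without control replicate 3, 4 or 5 or knockout replicate 1, 2 or 5. DESeq2 and limma-voom also called 0, with 45 of 1105 and 23 of 457 at an unadjusted p under 0.05. Most intervals were wide enough to hold moderate changes: the median half-width of the 95% interval was 0.53 on the log2 scale, against a median absolute log2 fold change of 0.24.

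Among miRNAs with a lower mean in knockout, those with the smallest p were miR-700-3p, miR-708-5p, miR-133a-3p, miR-30a-5p and miR-133b-3p. miR-708-5p, encoded in an intron of Tenm4 (chromosome 7, 96249424 to 96249532), was at 15.7 ± 7.93 CPM in controls and 7.67 ± 2.68 CPM in knockouts (SD, n = 5 per group, as for all CPM values). Its log2 fold change was -1.02 ± 0.38 (SE), and all 5 knockout libraries were below the control mean. miR-700-3p, whose hairpin overlaps an exon of Rcan3 on chromosome 4, was a rare miRNA at 2.33 ± 0.45 and 1.16 ± 0.42 CPM. miR-133a-3p, a muscle miRNA encoded beside miR-1a on chromosomes 2 and 18, was at 1620 ± 340 CPM in controls and 1177 ± 211 CPM in knockouts. Its log2 fold change was -0.46 ± 0.17 (SE), and its close relative miR-133b-3p had a log2 fold change of -0.56 ± 0.22. Among miRNAs with a higher mean, the smallest p values belonged to miR-543-3p, miR-223-5p, miR-369-3p, miR-21a-3p and miR-376b-3p. miR-21a-3p, the minor arm of the miR-21a hairpin within Vmp1, was at 14.9 ± 6.66 CPM in controls and 29.5 ± 15.3 CPM in knockouts, a log2 fold change of 0.98 ± 0.39. miR-369-3p was at 134 ± 53.3 and 223 ± 71.7 CPM, and miR-543-3p at 9.04 ± 2.23 and 14.7 ± 4.86 CPM; both lie in the Dlk1-Dio3 cluster. The myeloid miR-223-5p was at 6.90 ± 1.85 and 10.9 ± 3.48 CPM, with all 5 knockout libraries above the control mean. Unadjusted p values of these 10 ran from 0.013 to 0.030, and each had an adjusted p of 0.64 in edgeR's quasi-likelihood test.

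**Figure D1:**
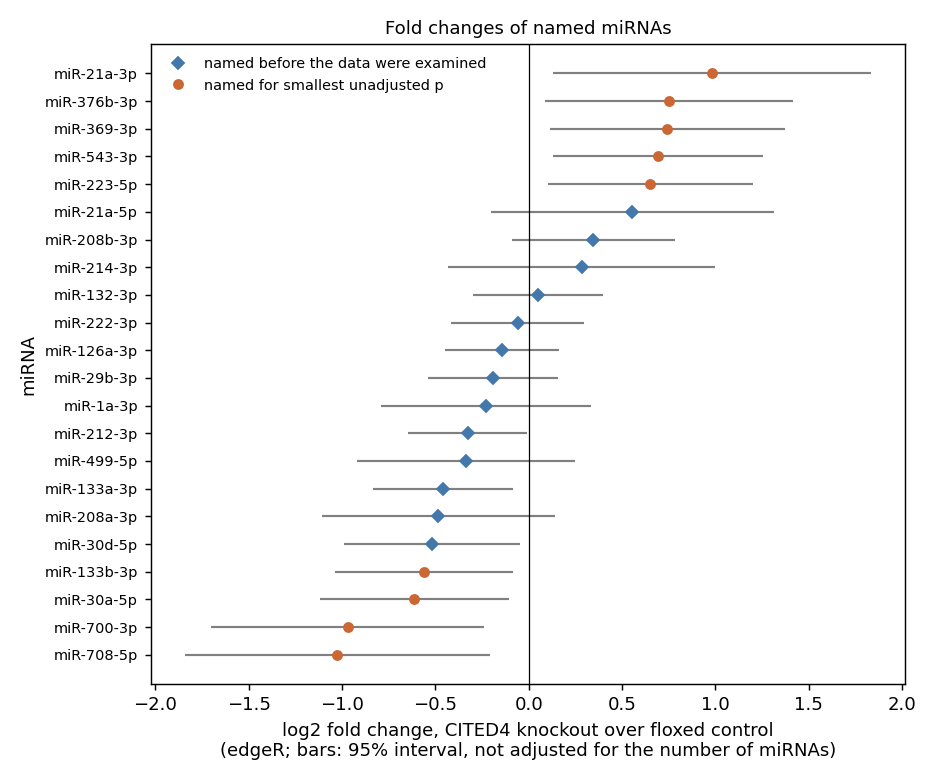
log2 fold changes (knockout over control, horizontal axis) of the 22 miRNAs named in advance (blue diamonds) or for their small p (orange circles), with 95% intervals as bars. The intervals of miR-30d-5p, miR-133a-3p and miR-212-3p lie below 0 before adjustment, that of miR-21a-5p spans it, and none of the 22 passed the adjusted test.

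miR-30d-5p, a member of the miR-30 family that is abundant in heart muscle, was chosen in advance. Its hairpin lies on chromosome 15 (68341208 to 68341289, GRCm38), in an exon of the long noncoding RNA Gm20732. It was at 20840 ± 4066 CPM in controls and 14540 ± 4142 CPM in knockouts, a log2 fold change of -0.52 ± 0.22 (SE) with a 95% interval from -0.99 to -0.05. All 5 knockout libraries were below the control mean, with an unadjusted p of 0.034 and an adjusted p of 0.64 in edgeR's quasi-likelihood test. The family as a list was lower in knockout, with 5 of 5 members negative and a median log2 fold change of -0.52 (camera adjusted p = 0.00044). With an estimated correlation between members of 0.87, the list did not pass (adjusted p = 0.75 with an estimated correlation), nor did its mean per library, which was 0.49 lower on the log2 scale (exact permutation test, p = 0.087, adjusted p = 0.54). miR-30a-5p was at 29529 ± 6892 and 19295 ± 5570 CPM, and miR-30e-5p, encoded in an intron of Nfyc, at 6509 ± 2162 and 4241 ± 1212 CPM. Adjusted over the list alone, 0 of 5 members passed, with a smallest adjusted p of 0.056, and over all miRNAs tested 0 passed in edgeR's test.

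Muscle-enriched miRNAs did not pass as a list (7 tested, 5 negative, median log2 fold change -0.34, camera adjusted p = 0.11). miR-208a-3p, encoded within the adult heart myosin gene Myh6 on chromosome 14, was at 603 ± 253 CPM in controls and 431 ± 121 CPM in knockouts. miR-208b-3p, encoded within the fetal myosin gene Myh7, was at 181 ± 41.4 and 231 ± 57.7 CPM, with a log2 fold change of 0.35 against -0.48 for miR-208a-3p. The intervals of both held 0. miR-499-5p, encoded within Myh7b, had a log2 fold change of -0.34 ± 0.27 (SE) and miR-1a-3p one of -0.23 ± 0.26. Adjusted over the list alone, 0 of 7 passed, with a smallest adjusted p of 0.085. The miR-29 family, whose members target collagen transcripts, had 3 of 3 members negative with a median of -0.27 (camera adjusted p = 0.063). miR-29c-3p was at 3173 ± 1138 and 2154 ± 583 CPM, while miR-29b-3p was at 228 ± 46.6 and 199.9 ± 24.3 CPM. None of its 3 members passed when adjusted over the list alone. Without control replicate 1 both lists passed (camera adjusted p = 0.045 for the muscle list and 0.047 for miR-29), and without control replicate 2 the miR-29 family did (0.018).

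The Dlk1-Dio3 list, miRNAs of an imprinted locus expressed from the maternal chromosome, was higher in knockout (39 tested, 36 positive, median log2 fold change 0.48, camera adjusted p = 7.3e-11). With an estimated correlation of 0.65 the list did not pass (adjusted p = 0.75 with an estimated correlation), and its mean per library was 0.51 higher on the log2 scale (exact permutation test, p = 0.13, adjusted p = 0.54). The 39 miRNAs lay between 109571990 and 109743795 on chromosome 12. miR-411-5p was at 131 ± 51.7 and 201 ± 56.5 CPM, and miR-376b-3p at 2.39 ± 1.02 and 4.08 ± 0.55 CPM. The 3 members with a lower mean, named after their values were seen, were miR-668-3p, miR-409-5p and miR-370-3p, each under 4 CPM. Adjusted over the list alone, 0 of 39 passed, with a smallest adjusted p of 0.20; 9 had an unadjusted p under 0.05 in edgeR's test.

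**Figure D2:**
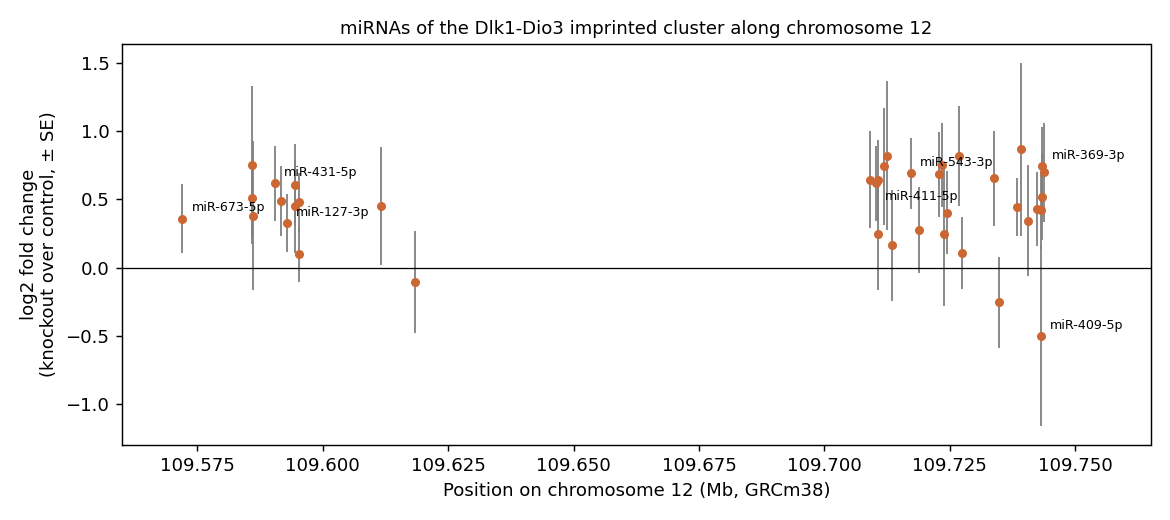
log2 fold change (knockout over control, vertical axis, bars are SE) of the 39 tested miRNAs of the Dlk1-Dio3 cluster by hairpin position on chromosome 12 (Mb, GRCm38). Points lie above 0 for 36 miRNAs along both parts of the locus, with miR-369-3p at 0.74 and miR-409-5p, a rare miRNA, at -0.50.

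The fibroblast and mesenchymal list was higher in knockout, with 10 of 10 members positive and a median log2 fold change of 0.34 (camera adjusted p = 0.024). It did not pass with an estimated correlation of 0.68 (adjusted p = 0.78 with an estimated correlation). miR-21a-5p, an abundant miRNA known to rise in cardiac fibrosis, was at 52572 ± 28415 CPM in controls and 77287 ± 25544 CPM in knockouts, a log2 fold change of 0.56 ± 0.35 (SE). miR-199a-3p was at 13638 ± 6176 and 17891 ± 4935 CPM, and miR-214-3p, encoded with miR-199a in Dnm3os, at 153 ± 84.8 and 186 ± 60.3 CPM. Adjusted over the list alone, 0 of 10 passed, with a smallest adjusted p of 0.51 in edgeR's test. The camera result was lost, with adjusted p values of 0.098, 0.054, 0.11, 0.095 and 0.085, without control replicate 3, 4 or 5 or knockout replicate 2 or 5.

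The erythroid list was lower in knockout, with 4 of 4 tested members negative and a median log2 fold change of -0.49 (camera adjusted p = 0.025, and adjusted p = 0.75 with an estimated correlation of 0.93). Of the 5 members fixed, miR-451a was not among the deposited miRNAs. Both miR-144-3p and miR-144-5p are arms of the same hairpin, so the 4 tested members are not separate measurements. miR-486a-5p, also made in muscle, was at 23545 ± 7516 and 16713 ± 5244 CPM, and shared all its counts with miR-486b-5p. miR-144-3p was at 485 ± 289 and 311 ± 182 CPM. With identical rows counted once the list no longer passed (adjusted p = 0.070). It was also lost without control replicate 3, 4 or 5 or knockout replicate 1, with adjusted p values of 0.098, 0.054, 0.098 and 0.095. Adjusted over the list alone, 0 of 4 passed, with a smallest adjusted p of 0.16. Of the 4 lists called, 2 passed without control replicate 3, 4 or 5, and 0 passed with the first principal component of the libraries as a covariate, chosen after seeing the data (camera adjusted p = 0.27 for miR-30, 0.72 for Dlk1-Dio3 and for fibroblast, 0.94 for erythroid).

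**Figure D3:**
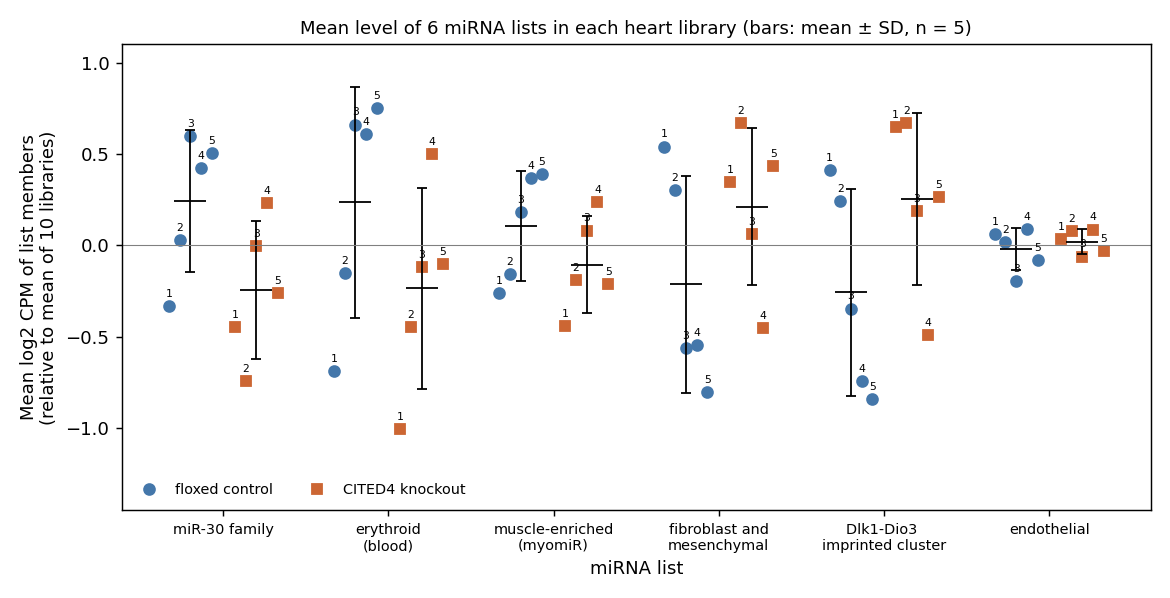
Mean log2 CPM of the members of 6 lists in each library, relative to the mean of the 10 libraries (vertical axis); blue circles are controls, orange squares knockouts, digits the replicate numbers, and black bars mean ± SD (n = 5). The groups overlap in all 6 lists, with control replicate 1 near the knockouts and knockout replicate 4 near control replicates 3 to 5 in the miR-30, erythroid, fibroblast and Dlk1-Dio3 lists.

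Markers of the other cell types of a whole heart did not pass as lists. The endothelial list had 3 positive and 4 negative of 7 members (camera adjusted p = 0.92), and miR-126a-3p, the main endothelial miRNA, was at 22874 ± 2497 and 20703 ± 2610 CPM. The smooth muscle list had 2 positive and 2 negative members (adjusted p = 0.85, its direction turned with library totals only), and miR-145a-5p was at 536 ± 128 and 453 ± 41.4 CPM. The leukocyte list had 4 positive and 5 negative of 9 members (adjusted p = 0.85), with miR-142a-5p at 112 ± 11.7 and 93.7 ± 10.8 CPM. The list of epithelial and other organ miRNAs had 7 positive and 4 negative members (adjusted p = 0.85). The medians of these lists were -0.06, 0.04, -0.07 and 0.05, and the sign of the median differed from that of the mean or of the test in each of the 4. In each of the 4, 0 members passed when adjusted over the list alone.

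Among miRNAs linked to hypertrophy, the list raised in pathological hypertrophy had 11 positive and 7 negative of 18 members (median log2 fold change 0.14, camera adjusted p = 0.46). miR-212-3p, which is known to promote cardiac hypertrophy, was at 39.8 ± 3.84 and 31.7 ± 4.20 CPM with a log2 fold change of -0.33 ± 0.15, while miR-132-3p of the same cluster was at 98.5 ± 19.5 and 102 ± 11.2 CPM. The list linked to physiological hypertrophy had 4 positive and 6 negative of 10 members (median -0.15, adjusted p = 0.46). miR-222-3p, a miRNA raised by exercise, was at 26.6 ± 4.31 and 25.5 ± 3.53 CPM, with a log2 fold change of -0.06, a 95% interval from -0.42 to 0.30, and a positive sign (0.05) when scaled by library totals only. The hypoxia and stress list had 4 positive and 2 negative members (adjusted p = 0.53), with miR-210-3p at 306 ± 79.8 and 352 ± 87.0 CPM. The let-7 family had 7 positive and 2 negative of 9 members (median 0.05, adjusted p = 0.48), the miR-15/16 family 2 and 4 (median -0.08, adjusted p = 0.53), and the miR-17-92 clusters 4 and 5 (median -0.05, adjusted p = 0.71). For each of these lists, 0 members passed when adjusted over the list alone or over all miRNAs.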

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

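Each of the 69 values (66 named miRNAs and 3 library measures) was examined in both groups for a library far from the other 4, by the gap to its nearest neighbour as a share of the group's range. In 8 of 138 groups this share was above the 95% critical value for 5 samples, 0.71, where chance alone gives 1 in 20, or 6.9. Control replicate 3 stood apart in 3 of the 8. Its let-7e-5p level was 1484 CPM against 2716 to 2867 CPM in the other controls (share of the range 0.890). Its miR-15b-5p level was 839 CPM against 1008 to 1070 CPM (0.732), and its miR-19a-3p level was 56.2 CPM against 24.4 to 32.9 CPM (0.730). Control replicate 1 had 12.9 CPM of miR-543-3p against 7.53 to 8.85 CPM (0.755). Control replicate 4 had 2.59 CPM of miR-342-5p against 4.68 to 5.38 CPM (0.748). Knockout replicate 4 stood apart for miR-22-3p, at 6183 CPM against 3581 to 4278 CPM (0.732), and for miR-499-5p, at 3815 CPM against 1820 to 2396 CPM (0.711). Knockout replicate 3 had 25640 CPM of miR-143-3p against 30905 to 32415 CPM (0.777).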

How the results depend on the processing

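The fits with the component or surrogate variable, thinning, identical counts used once and the exact permutation of list means were chosen after seeing the data. The count of 0 miRNAs past the threshold, in either direction, was the same in all 25 alternative fits. The smallest adjusted p ranged from 0.15 with the replicate block to 1.00 with the first principal component as a covariate. Among miRNAs at an unadjusted p under 0.05, the count of 29 of 457 became 102 of 1105 without a low-count filter. With the stricter filter it was 16 of 278, and with DESeq2 45 of 1105. Of 457 miRNAs each, it was 14 with library totals only, 99 with sample weights and 72 with the replicate block. With the component or surrogate variable it was 7 and 8 of 457. It ranged from 6 to 84 with 1 library left out. Library totals only moved the median log2 fold change of all miRNAs from 0.03 to 0.14. The replicate block changed no call of a miRNA or list, with 4 lists called. Same-number pairs correlated between -0.12 and 0.45 in their deviations, and 4 of 10 libraries correlated best with their own number. The 4 called lists became 0 with an estimated correlation, with fry, with the exact permutation test, and with the component or surrogate variable. They became 6 with sample weights, 5 without a low-count filter, 3 with the stricter filter, with limma on normalized values and with identical counts used once, and 2 to 6 with 1 library left out, with 2 without control replicate 3, 4 or 5. For the miR-30 family, the adjusted p was 0.75 with an estimated correlation, 0.65 with fry, 0.54 by permutation, 0.27 with the component and 0.53 with the surrogate variable. For the Dlk1-Dio3 cluster these were 0.75, 0.65, 0.54, 0.72 and 0.89. For the fibroblast list they were 0.78, 0.65, 0.54, 0.72 and 0.57, the last pair with the direction turned, and from 0.0013 to 0.11 with 1 library left out. For the erythroid list they were 0.75, 0.65, 0.54, 0.94 and 0.89, the last pair turned in direction, with 0.052 under the stricter filter, 0.062 with limma on normalized values, 0.070 with identical counts used once, and from 0.0024 to 0.098 with 1 library left out. The miR-30 and Dlk1-Dio3 lists passed in each fit with 1 library left out. Because the component was built from all libraries, it also removes the part of a genotype effect that lies along it. These losses therefore do not show whether a genotype effect or other variation was removed. For the other losses the cause was not tested.

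Of 432 alternative list results, 32 turned in direction, and 0 of these passed. With the component the adjusted p was 0.938 for the muscle, pathological, physiological, smooth muscle and hypoxia lists and 0.940 for the miR-17-92 and endothelial lists. With the surrogate variable it was 0.902 for the muscle, physiological, smooth muscle and hypoxia lists, 0.891 for the pathological list, 0.982 for miR-17-92 and 0.987 for the endothelial list. The endothelial list also turned with sample weights (0.919) and without the most abundant miRNA (0.946), the smooth muscle list with library totals only (0.956), the leukocyte list without a low-count filter (0.982) and by permutation (0.709), and the epithelial list under the stricter filter (0.932). With 1 library left out, direction turned without control replicate 3 for let-7 (0.054 to 0.931 over all left-out libraries), miR-17-92 (0.468 to 0.962), endothelial (0.782 to 0.991, also without knockout replicate 4) and smooth muscle (0.668 to 0.996, also without knockout replicate 3). It turned without knockout replicate 3 for the leukocyte list (0.490 to 0.996) and without knockout replicate 2 for the epithelial list (0.634 to 0.991).

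Of 1641 alternative values of the 66 named miRNAs, 1597 kept the sign and 44, of 20 miRNAs, did not, 27 of them with a covariate; 0 passed. With the component the log2 fold changes were miR-214-5p -0.018, miR-144-5p 0.081, miR-144-3p 0.31, miR-499-5p 0.093, miR-34c-5p -0.15, miR-34b-3p -0.21, miR-221-3p -0.022, miR-210-3p -0.074, miR-1a-3p 0.091, miR-214-3p -0.13, miR-203-3p 0.041 and miR-195a-5p 0.019. With the surrogate variable they were miR-208a-3p 0.014, miR-30b-5p 0.0042, miR-214-5p -0.049, miR-144-5p 0.099, miR-199a-3p -0.010, miR-144-3p 0.37, miR-499-5p 0.12, miR-34c-5p -0.19, miR-34b-3p -0.25, miR-221-3p -0.027, miR-210-3p -0.086, miR-1a-3p 0.12, miR-214-3p -0.16, miR-203-3p 0.050 and miR-195a-5p 0.031. With library totals only miR-222-3p was at 0.054 and miR-143-3p at 0.099, and with thinning they were at 0.0072 and 0.011. miR-143-3p was at 0.00081 with upper-quartile factors, 0.010 without a low-count filter and 2.8e-05 with identical counts used once, and miR-132-3p at -0.019 with sample weights. With 1 library left out, miR-19a-3p ranged from -0.27 to 0.11, miR-145a-3p from -0.0029 to 0.21, miR-222-3p from -0.12 to 0.056, miR-132-3p from -0.029 to 0.14 and miR-143-3p from -0.052 to 0.052. The share of counts was 1.83 percentage points lower in knockout for the most abundant miRNA and 0.413 points higher for the 5 most abundant. Library totals kept their direction in all alternatives. List tests by DESeq2 were not run. Of 457 miRNAs, 417 had a 95% half-width under 1 on the log2 scale. The half-width was 1 or more for 36 of 181 miRNAs with a mean under 10 CPM and for 4 of the other 276, among them miR-144-3p and miR-34c-5p, so wide intervals were not confined to rare miRNAs.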

Other observations

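Several genomic clusters and families not fixed as lists had means mostly on one side of the control level, although 0 of their members passed edgeR's adjusted test. They were picked as groups after their values were seen; some members, such as miR-34b-5p, miR-34b-3p, miR-34c-5p and miR-708-5p, stand in a fixed list or were named by the rule, and miR-34c-5p also counts in the fibroblast list. The miR-34b/c hairpins on chromosome 9, known as targets of the tumour suppressor p53, had 4 of 4 mature miRNAs with a higher mean in knockout and a median log2 fold change of 0.57, signs that turned for miR-34b-3p (-0.21) and miR-34c-5p (-0.15) with the first component as a covariate. miR-34a-5p, from another locus, was at -0.0026 ± 0.13 (SE). The 3 tested miR-378 miRNAs had a median of -0.59, and miR-378a-3p was at 68470 ± 21264 CPM in controls and 46443 ± 16894 CPM in knockouts. Both arms of miR-708 had lower means, at -1.02 for the 5p arm and -1.09 for the 3p arm. The miR-181c/d cluster on chromosome 8 had 3 of 3 miRNAs with a lower mean and a median of -0.41. The miR-500 to miR-532 cluster on the X chromosome had 7 of 8 miRNAs with a higher mean and a median of 0.23. Of 136 hairpins with both arms tested, 103 had the same sign in both arms, and the log2 fold changes of the arms correlated with r = 0.68 across hairpins, which are not independent replicates.

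The fits with thinned counts and with the component as a covariate, the splits for the count of 0 called miRNAs and the permutation of the within-group component were tests chosen after the result they bear on was seen. The 29 miRNAs at an unadjusted p under 0.05 were matched or exceeded by 17 of 100 splits of the 10 libraries into 5 and 5, the real one included, with 188 as the highest of the others, and the 4 lists by 36 of 100, with 8 as the highest, so chance cannot be excluded for either. For the count of 0 called miRNAs the splits decide nothing, since any split gives at least 0 (100 of 100). The highest other split called 136 miRNAs and set control replicates 1 and 2 and knockout replicates 1, 2 and 5 against the other libraries, which points to a structure of the libraries that crosses genotype.

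That structure was an axis present within both groups. The first component of the deviations from the group means held 42.5% of their variance. In 1000 permutations of each miRNA among the libraries of a group it held at most 20.9% (p = 0.001, the smallest they can give). This argues against independent noise of single miRNAs. Rows with identical counts and arms of the same hairpin were not independent beforehand, so the permutations do not show what the axis is. In log2 units per SD of the axis, median slopes were 0.47 for the Dlk1-Dio3 list (38 of 39 members positive), 0.49 for the fibroblast list (10 of 10), -0.32 for miR-30 and -0.42 for the erythroid list. The muscle-enriched list was at -0.30 (SE 0.07 over members, 1 of 7 positive), the direction a lower share of cardiomyocytes would give. A lower share of cardiomyocytes, raising every other cell type alike, is argued against by the endothelial list. Its median slope was 0.00073 (SE 0.05 over members, which are not independent), with members from -0.17 to 0.19. The smooth muscle list was at -0.07. This holds only as far as these lists mark their cell types, which was not tested, and a change in the fibroblasts alone stays open. A hypothesis is that the axis may follow how far the heart tissue in each library had remodelled after constriction, which was not tested: pressure, heart weight and fibrosis were not analysed here.

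The log2 fold changes of genotype correlated with the slopes along the axis at r = 0.67 across miRNAs, which are not independent. From differences of mean log2 CPM, computed alike for every split, the absolute correlation was 0.685, and 14 of the 126 possible splits, the real one included, gave one at least as high. After thinning, each of the 4 list medians kept at least 0.901 of its value. Thinning keeps the expected share of each miRNA in its library. It therefore cannot decide whether a bias of preparation that goes with depth caused the list shifts. With the first component of all libraries as a covariate, the largest share kept was 0.334, that of the miR-30 family. Whether genotype moved the samples along the axis or the groups differed on it by chance cannot be told apart, because the component would absorb a genotype effect as well and its own difference between groups was within the spread of the libraries (exact two-sided permutation test, p = 0.17).

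For the erythroid list, less blood left in the knockout hearts may explain the lower values. miR-144-3p, an erythroid miRNA and itself a member of the list, had a log2 fold change of -0.64. Its 95% interval from -1.68 to 0.40 holds both the list's median of -0.49 and 0. Less blood and no difference in blood content therefore cannot be told apart.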
